A study of Mus musculus with 6 samples.

How the data were processed

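Prostate tissue of 3-month-old C57BL/6 mice was digested with collagenase I and trypsin, epithelial cells were isolated by flow sorting and total RNA was taken, per the labels' protocols. The labels name both a bulk RNA library kit (NEBNext Ultra RNA) and a droplet single-cell 3' kit for these libraries. The table holds 1 value per gene and library, and which of the kits was used could not be settled from it. Sequencing was on an Illumina HiSeq instrument, per the labels. The marker used for sorting is not given in the sources used here. There were 6 libraries, 3 from control mice and 3 from E-cadherin conditional knockout mice, grouped by the genotype label. Nothing in the labels says that each library came from a separate animal, so p-values measure the spread between these libraries, which may in part be technical.

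The submitters' processing notes name TopHat2 2.0.14, Cufflinks 2.2.1 and Cuffdiff, with the genome build GRCm38, without their role or order. The values were taken as FPKM, normalised for transcript length and library size by the authors. This unit was inferred from the tools in the submitters' processing notes and from the form of the values, since the header of the deposited table does not name it. The deposited table lists 632 genes, and how they were selected, the annotation version and any filter are not given in the sources used here. It also holds a mean per group, which equals the mean of the 3 libraries within a relative difference of 4.95e-06. All 632 gene identifiers matched GENCODE M21 (GRCm38), which gave positions and gene types. For 16 genes the symbol differed from M21, and 1 symbol had been turned into a date and was restored from its identifier. FPKM shares each library's total among genes, so a large rise in abundant genes lowers the values of the others.

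Depth is unknown. Low values were compared between pairs of control libraries, and 17 of 61, 18 of 79 and 16 of 62 ratios matched ratios of small whole numbers. After jittering the means were 9.4, 11.5 and 9.9 and the maxima 10, 14 and 12. The matches exceeded these, but most ratios did not match, and reads were not recovered from them. No interval that needs depth is given. The listed genes summed to between 31468 and 36565 FPKM per library, which is not a depth. No pair of libraries held identical values.

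Because per-library values were given only for selected genes, limma 3.58.1 (R 4.3.3) with a mean-dependent prior was run on log2(FPKM + 1) for the listed genes, with Benjamini-Hochberg adjustment over the 632 and a threshold of 0.05. The pseudocount of 1 understates the change of low genes. Folds in the text are ratios of group means with no pseudocount. On simulated data with the 632 genes, this step called 41.8% of genes changed 1.5-fold, 68.7% changed 2-fold, 89.4% changed 4-fold and 1.16% of unchanged genes. The simulation shuffled the SDs between genes and left 432 genes unchanged. Its rates therefore do not carry over to a list selected on these libraries. Since the list was selected on the same libraries, adjustment was repeated as if all 21951 annotated protein-coding genes or all 55450 annotated genes had been tested. Sample titles shared no replicate numbers, so no pairing was used.

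The 34 gene lists were fixed before the data were examined, and 4 more, on the amino acid response, squamous epithelium, complement and adipocytes, were written afterwards. Lists with at least 5 listed genes were tested for direction with a two-sided Fisher's exact test against the other listed genes, adjusted over 10 lists. In 1000 random lists, 3.8% had p under 0.05. The same lists were tested by camera against the other listed genes, with the preset and with an estimated correlation, as an alternative. The median sizes of rises and falls were compared by a permutation test with 100000 resamples. Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 was used.

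Named genes were set by a rule fixed before the data were examined. It took Cdh1 first, then, among called genes with a finite fold and at least 1 FPKM in the higher group, the 10 largest rises and the 10 largest falls, then the 5 called genes with the highest level in each group. Up to 4 called members of each fixed list with at least 3 listed genes were added, those with the largest change. This gave 80 genes. The 36 predicted or unnamed genes were counted and not named. Other genes are named where a list had few listed members, and were chosen after their values were seen. Some genes that the rule or a list would name are counted and not reported by name here.

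Alternatives fixed in advance were a threshold of 0.01, log2 ratios of at least 1 and 2, minimum levels of 1 and 5 FPKM, a pseudocount of 0.1, leaving out genes at 0, predicted genes or each library in turn, and centring on the median ratio of the listed genes. Added after the values were seen were the adjustments over annotated genes, unmoderated variances and centring on the midpoint of the gap in log2 ratios. Centring was first done by subtracting the shift after the pseudocount was added. That shifts low genes by more than their values were scaled, and after its results had been seen it was replaced by dividing the knockout FPKM before the pseudocount. The counts of both forms are given with the alternatives.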

Results

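RNA was sequenced from sorted prostate epithelial cells of C57BL/6 mice at 3 months of age, in 3 control libraries and 3 libraries from mice with a conditional knockout of E-cadherin, the main adhesion receptor between epithelial cells. The table analysed holds 632 genes that the authors had selected, with a value in FPKM, read fragments scaled by transcript length and library size, for each library. How the genes were selected is not given in the sources used here, and the sequencing depth behind the values is unknown. On the log2(FPKM + 1) scale, the correlation across these genes was 0.957 to 0.977 between libraries of the same group. Between libraries of different groups it was 0.891 to 0.940. Genes are not independent replicates, and a list selected on these libraries favours a higher correlation within groups, so these values are no evidence that the groups separate. Values below are mean FPKM ± SD over n = 3 libraries per group, folds are ratios of group means, and adjusted p-values are from limma over the 632 listed genes. Because the list was chosen on these libraries, these p-values describe a selected list and are not independent evidence of a difference. Every control title carries the mark L2 and every knockout title the mark L7, so a difference that goes with these marks cannot be told apart from genotype.

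The comparison asks how the transcriptome of prostate epithelium differs between the conditional knockout mice and their control littermates, in a study concerned with cell polarity and spindle orientation. Cdh1, the gene of E-cadherin (chromosome 8, 106603351 to 106670246, GRCm38), was not among the 632 genes and was not analysed here, so the genotype labels could not be checked on the targeted gene. None of the 17 genes of a fixed adherens junction list, the 26 of a polarity list, the 15 of a spindle orientation list or the 17 of a Notch list was among the 632, and these lists were not analysed here. Of 18 tight junction genes 1 was listed, the claudin Cldn10, at 19.4 ± 5.43 FPKM in control and 14.0 ± 2.85 in knockout cells, which did not pass limma (adjusted p = 0.15) and was called as fallen without control replicate 3 (adjusted p = 0.0453). Of 15 desmosome and hemidesmosome genes 1 was listed, the hemidesmosomal collagen Col17a1, which rose 2.29-fold. Adjusted over the list alone, 0 tight junction genes and 1 desmosome or hemidesmosome gene passed. This adjustment, also given for the lists below, covers only listed members, which had been selected on these same libraries. Passing it is therefore no added support, and with 1 listed gene it is the unadjusted p.

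Most listed genes were higher in the knockout libraries. Of the 632 genes, 450 were higher in knockout and 182 lower, and limma called 413 as risen and 46 as fallen. The direction differed by level. At 1 to 10 FPKM 249 genes were higher and 36 lower, and at 10 to 100 FPKM 134 and 96. At 100 FPKM and above falls outnumbered rises, with 26 genes higher and 48 lower. The number of falls was 20 without control replicate 1, 79 without control replicate 2, 24, 25 and 22 without knockout replicates 1, 2 and 3, and 119 on the midpoint scale described below. The group values did not overlap for 522 genes, 82.6% of the list. Chance gives 10% for 3 libraries against 3 among unselected genes, which is no reference for genes selected on these libraries. Rises were larger than falls, with a median fold of 2.25 over 441 genes with a finite ratio against 1.34 over 181. The difference in median absolute log2 ratio was 0.75 across genes, which are not independent replicates (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). It was 0.40 with a pseudocount of 1 and 0.46 on the midpoint scale, and part of it follows from the limits of the list, which holds falls from a log2 ratio of about -0.26 and rises only from about 0.56 (1% bounds).

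The largest rises included secreted, immune and epithelial genes. Spp1, the gene of osteopontin, rose 15.6-fold from 0.308 ± 0.093 to 4.81 ± 1.67 FPKM, and the monocyte chemokine gene Ccl8 (chromosome 11, 82115185 to 82116799) rose 10.4-fold from 4.74 ± 1.30 to 49.2 ± 3.87 FPKM (limma log2 difference 3.15, SE 0.20, adjusted p = 0.00061). Sprr1a, a cornified envelope precursor (chromosome 3, 92483952 to 92485895), rose 9.86-fold from 12.7 ± 6.13 to 125 ± 22.1 FPKM (limma log2 difference 3.28, SE 0.31, adjusted p = 0.0012). Calcb, a calcitonin gene-related peptide gene, rose 10.2-fold and the glucuronosyltransferase gene Ugt2b35 rose 10.8-fold. The other 5 of the 10 largest rises were the immunoglobulin genes Igkv6-13, Ighv1-50, Ighv1-55, Ighg3 and Igkv12-44. Igkv6-13 went from 0.0447 ± 0.077 to 6.61 ± 4.86 FPKM, with control libraries 2 and 3 listed at 0. Some of these folds moved by over 1.5 times without 1 library. Without control replicate 1, Calcb was 15.3-fold, Ighv1-55 22.0-fold and Ighv1-50 55.4-fold higher. Ighv1-50 was 16.3-fold higher without control replicate 3 and Ugt2b35 16.6-fold without control replicate 2. Igkv12-44 was 5.56-fold higher without knockout replicate 1, and Igkv6-13 was 91.9-fold higher without knockout replicate 2.

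The largest falls included secretoglobin genes. Scgb1b7 (chromosome 7, 31712665 to 31713978) fell from 1.61 ± 0.24 to 0.013 ± 0.022 FPKM, with knockout libraries 2 and 3 listed at 0 (limma log2 difference -1.36, SE 0.098, adjusted p = 0.0007). The secretoglobin genes Scgb2b7, Scgb2b27 and Scgb2b17 were 12.9-fold, 5.12-fold and 3.75-fold lower, and all 3 fell. Wfdc3, a member of the whey acidic protein family (chromosome 2, 164731180 to 164745931), fell 3.11-fold from 458 ± 110 to 147 ± 16.7 FPKM (limma log2 difference -1.61, SE 0.20, adjusted p = 0.0016). G6pc2, Speer4c, the class Ib histocompatibility gene H2-Q10, Sbpl and Fam195b also fell, by ratios of 16.4, 3.64, 2.46, 2.13 and 2.11. Without control replicate 1, Scgb2b7 was 7.05-fold and Speer4c 2.21-fold lower. Without knockout replicate 1, Scgb2b7 was 38.1-fold and Scgb2b17 5.90-fold lower and Scgb1b7 was at 0 in the remaining knockout libraries. Without knockout replicate 2, Scgb2b27 was 11.4-fold and G6pc2 34.1-fold lower. Secretoglobins, Speer genes and immunoglobulin segments have near-identical copies, so the assignment of reads to single members is uncertain. With 1 library left out, limma did not call H2-Q10 without control replicate 1 or 2 or knockout replicate 1 or 3 (adjusted p = 0.0661 to 0.0855), Sbpl without control replicate 1 or 3 or knockout replicate 3 (0.0702 to 0.122) or Speer4c without control replicate 3 or any 1 knockout replicate (0.0613 to 0.0970).

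**Figure D1:**
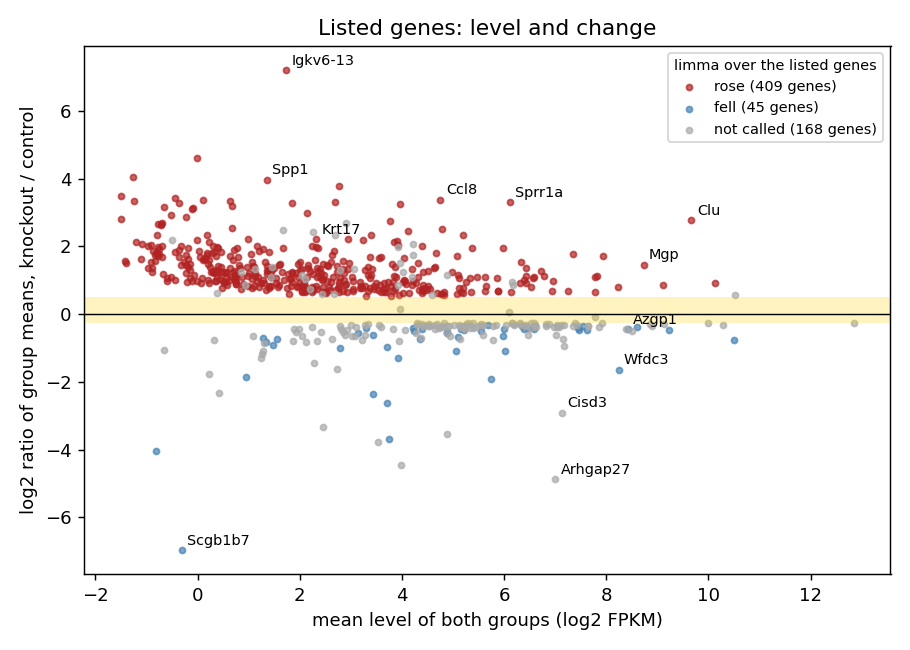
Each point is 1 listed gene with a finite ratio, with the mean of both groups on the x axis (log2 FPKM) and the log2 ratio of group means, knockout over control, on the y axis. Red points rose and blue points fell by limma over the listed genes, grey points were not called, and the yellow band from -0.25 to 0.5 holds 3 of the 632 genes.

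Among called genes the highest in control were Ly6e (773 ± 111 FPKM), Wfdc3, Fgl1, Azgp1 and Apoe, and the highest in knockout were Ly6e (1456 ± 32.2), Clu, Apoe, Mgp and S100a11. Ly6e rose 1.88-fold, the apolipoprotein gene Apoe 1.83-fold from 392 ± 44.1 to 716 ± 27.7 FPKM, and S100a11, a calcium-binding protein gene, 1.74-fold. Mgp, which encodes an inhibitor of calcification (chromosome 6, 136872435 to 136875823), rose 2.74-fold from 227 ± 13.4 to 622 ± 8.59 FPKM. The chaperone gene Clu (chromosome 14, 65968483 to 65981547) rose 6.86-fold from 207 ± 112 to 1418 ± 204 FPKM.

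The number of called genes depended on how the selection is treated. With the adjustment made as if all 21951 annotated protein-coding genes had been tested and no unlisted one had changed, limma called 23 genes as risen and 1 as fallen, and over all 55450 annotated genes 1 and 0. Rises made up 90.0% of the calls on the deposited scale and 76.6% on the midpoint scale. There knockout values were divided so that the gap between the smallest rises and falls is centred on 0 (a log2 shift of 0.15). With values centred on the median ratio of the listed genes (a shift of 0.93) the share was 30.3%. This centring puts about as many listed genes below 0 as above by construction (312 lower, 320 higher). A gene described as lower on that scale had a ratio under that of the median listed gene, and this alone does not speak against its rise.

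Genes of immune cells were higher in knockout libraries. Of 24 fixed myeloid genes 15 were listed and all 15 rose, and adjusted over the list alone 15 passed. Their median rise was 2.12-fold, while 2 of the 15 were lower on the scale centred on the listed genes. Ptprc, the pan-leukocyte antigen CD45, rose from 1.55 ± 0.50 to 3.92 ± 0.35 FPKM, the monocyte chemokine receptor gene Ccr2 rose 2.55-fold, the macrophage gene Aif1 2.50-fold and the integrin gene Itgax 2.25-fold. The split of the myeloid genes differed from that of the other listed genes (two-sided Fisher's exact test, adjusted p = 0.0434 over 10 lists), and without control replicate 1, where all 15 were still higher, the adjusted p was 0.0752. Fisher's exact test treats genes as independent. By camera over the listed genes this list passed with the preset correlation (adjusted p = 0.0137) and not with the correlation of 0.642 estimated between its members (adjusted p = 0.628, where 0 of the 10 lists passed). Since most listed genes are higher, a rise of 10 or fewer listed genes cannot reach p = 0.05 in Fisher's exact test, which holds for 7 of the 10 lists. Among genes with a log2 ratio of at least 1 or at a limma adjusted p of 0.01 too few falls remain for a rise of this list to pass (adjusted p = 1 in both). Of 21 lymphoid genes 5 were listed and all 5 rose, with a median of 3.29-fold, and adjusted over the list alone 5 passed. All 5 are genes of B cells or plasma cells, so they do not speak to other lymphoid cells. The B cell receptor gene Cd79a rose 9.77-fold and Cd79b 3.68-fold, and the immunoglobulin constant genes Ighm and Igkc rose from 15.7 ± 3.80 to 51.8 ± 3.64 FPKM and from 115 ± 30.2 to 375 ± 95.2 FPKM. With 5 listed genes, all higher, Fisher's exact test (adjusted p = 0.411) could not have passed and says nothing on the lymphoid list. Control library 2 was 0.20 above the control mean on the myeloid list, on the log2(FPKM + 1) scale, and the knockout libraries were 0.92 to 0.95 above it.

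Chemokine and cytokine genes also rose. Of 36 on the fixed list 13 were listed and all 13 rose, with a median of 3.67-fold, and adjusted over the list alone 13 passed, while 4 of the 13 were lower on the scale centred on the listed genes. The number that rose was 11 without control replicate 1 or knockout replicate 2, 10 without control replicate 3, knockout replicate 1 or knockout replicate 3, and 12 on the midpoint scale, and the calls lost were among Ccl5, Csf1, Cxcl9 and Cxcl17. The neutrophil chemokine genes Cxcl1 and Cxcl2 rose 7.37-fold and 6.40-fold (Cxcl2 17.3-fold without control replicate 1), and the inflammatory cytokine gene Il1b rose 4.57-fold from 0.356 ± 0.112 to 1.63 ± 0.26 FPKM. All 13 being higher did not pass against the other listed genes (Fisher's exact test, adjusted p = 0.0824), and it passed without knockout replicate 1 (adjusted p = 0.0457).

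Genes of the interferon response and of antigen presentation rose. Of 28 on the fixed list 16 were listed and all 16 rose, with a median of 2.46-fold, and adjusted over the list alone 16 passed, while 2 of the 16 were lower on the scale centred on the listed genes. The antiviral gene Oas2 rose 5.09-fold from 0.374 ± 0.042 to 1.90 ± 0.21 FPKM, Oasl2 3.20-fold, Mx2 2.93-fold and Usp18, a protease that removes ISG15, 2.72-fold. The split differed from that of the other genes (Fisher's exact test, adjusted p = 0.0434) and not without control replicate 1 (adjusted p = 0.0752), where all 16 were still higher. By camera it passed with the preset correlation (adjusted p = 0.0137) and not with the estimated correlation of 0.246 (adjusted p = 0.628). Among genes with a log2 ratio of at least 1 or at a limma adjusted p of 0.01 too few falls remain for a rise of this list to pass (adjusted p = 1 in both). Cd74 is on both this list and the myeloid list.

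Acute phase and mucosal defence genes were mostly higher. Of 18 on the list 8 were listed, of which 6 rose and 2 were not called, and adjusted over the list alone 6 passed. The median ratio was 3.03-fold higher, and 7 of the 8 stayed higher on the scale centred on the listed genes. Besides Clu, the antimicrobial lectin gene Reg3g rose 4.09-fold, haptoglobin (Hp) 4.02-fold and Lrg1 3.49-fold from 11.4 ± 6.96 to 39.7 ± 7.24 FPKM. Saa3 was at 19.7 ± 26.7 FPKM in control, with 50.2 in control library 1, and at 11.3 ± 3.69 in knockout, and Lcn2 was at 48.8 ± 27.9 and 93.5 ± 30.4 FPKM. Both were not called. Control library 1 was 0.90 above the control mean on this list, on the log2(FPKM + 1) scale, and the rise of Reg3g passed with all libraries and without control replicate 1, and not without any other 1 library (adjusted p = 0.0518 to 0.105). The number of the 8 that rose was 7 without control replicate 1, where Lcn2 was called (adjusted p = 0.0495), 5 without control replicate 2 or 3 or knockout replicate 3, and 4 without knockout replicate 1 or 2, where Wfdc2 was lost as well. Without control replicate 1, Reg3g was 24.8-fold and Lrg1 5.34-fold higher, and without knockout replicate 1 Hp was 2.60-fold higher. With 8 listed genes the list was too short for a rise to pass Fisher's exact test (adjusted p = 0.5).

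**Figure D2:**
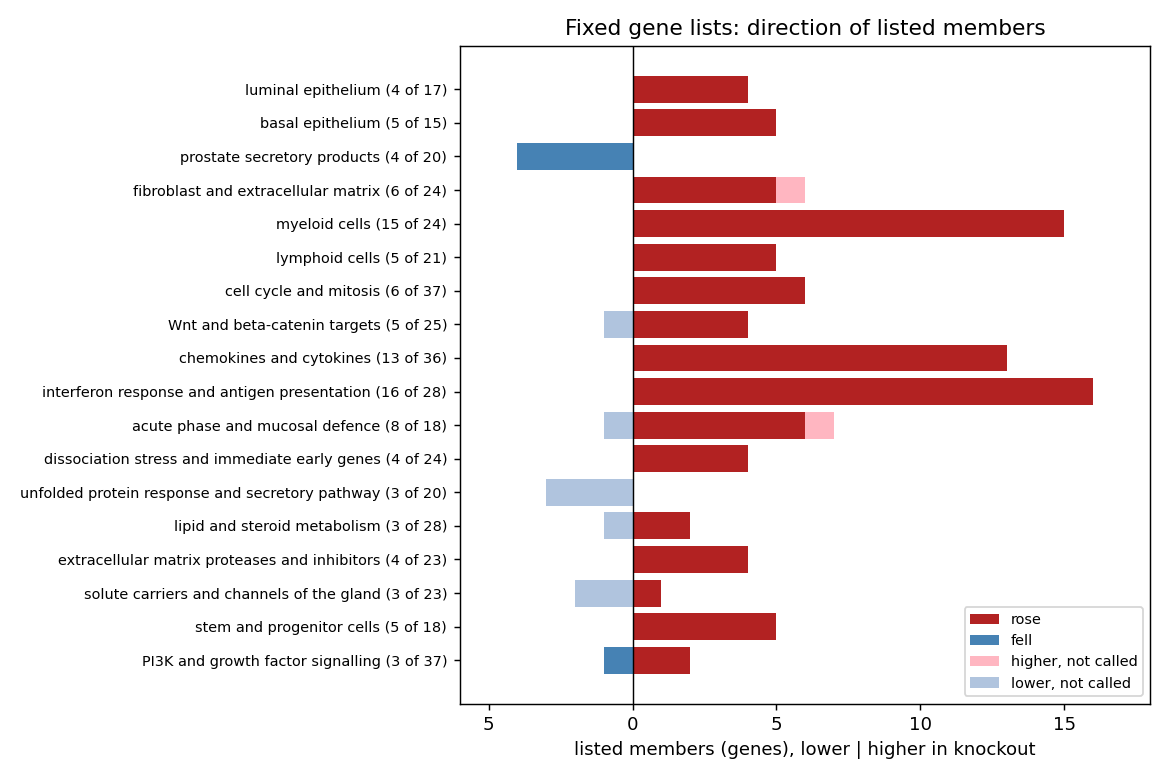
Bars give, for each fixed list with at least 3 listed genes, the number of listed members that were lower (left of 0) or higher (right) in knockout libraries, with called genes in dark and uncalled genes in light colours. All 15 myeloid and all 16 interferon and antigen presentation members rose on the deposited scale, and 2 of each were lower on the scale centred on the listed genes.

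Markers of basal and progenitor-like epithelium rose. Of 15 basal genes 5 were listed and all 5 rose, with a median of 1.997-fold, and adjusted over the list alone 5 passed, while 2 of the 5 were lower on the scale centred on the listed genes. Krt17 (chromosome 11, 100256217 to 100261029), a keratin of basal and stressed epithelium, rose 4.62-fold from 1.77 ± 0.26 to 8.19 ± 1.10 FPKM (limma log2 difference 1.73, SE 0.16, adjusted p = 0.0012). Col17a1 rose 2.29-fold, Krt15 from 56.2 ± 11.9 to 112 ± 13.1 FPKM and Krt14 1.70-fold. Of 17 luminal genes 4 were listed and all 4 rose, with a median of 2.84-fold, and adjusted over the list alone 4 passed, while 1 of the 4 was lower on the scale centred on the listed genes. Among them, Ly6a (Sca-1) rose from 73.9 ± 14.2 to 254 ± 38.3 FPKM, Psca 2.35-fold and Krt4 1.70-fold. Of 18 stem and progenitor genes 5 were listed and all 5 rose, with a median of 2.55-fold, and adjusted over the list alone 5 passed, while 1 of the 5 was lower on the scale centred on the listed genes. They include Ly6a again, the hyaluronan receptor gene Cd44, 2.55-fold, and Aldh1a3, 1.94-fold, while Runx1 was not called without knockout replicate 1 (adjusted p = 0.0554). With 5 listed genes each, the basal and stem lists were too short for a rise to pass Fisher's exact test (adjusted p = 0.411 for each). The luminal list had too few listed genes for that test.

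Listed genes of the fixed prostate secretory list were lower in knockout libraries. Of 20 on the list 4 were listed and all 4 fell, and adjusted over the list alone 4 passed, with a median log2 ratio of -0.44. Sbpl, a spermine-binding protein-like gene, fell 2.13-fold from 87.7 ± 25.3 to 41.2 ± 18.6 FPKM. The calcium channel gene Trpv6 was 1.36-fold lower, Azgp1 1.35-fold and Fgl1 1.30-fold, from 441 ± 38.3 to 340 ± 20.3 FPKM. The number that fell was 0 without control replicate 1, 3 without control replicate 2 and 1 without control replicate 3 or any 1 knockout replicate. Trpv6 was not called in any of these fits (adjusted p = 0.0538 to 0.135). Azgp1 was lost without control replicate 1 or any 1 knockout replicate. Fgl1 was lost without control replicate 1 or 3 or knockout replicate 1 or 2, and Sbpl without control replicate 1 or 3 or knockout replicate 3. Listed leukocyte and fibroblast genes were higher in the same libraries, and whether the cell mix lowered these genes was not tested.

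Fibroblast and matrix genes rose by smaller ratios. Of 24 on the list 6 were listed, of which 5 rose and Col5a2 was not called, and adjusted over the list alone 6 passed. Their median was 1.53-fold, and 5 of the 6 were lower on the scale centred on the listed genes. Lum rose 2.08-fold, Fbln1 1.62-fold, the collagen gene Col1a2 from 28.6 ± 6.02 to 44.4 ± 0.83 FPKM and Thy1 1.498-fold. Without control replicate 2 Col5a2 was called as risen (adjusted p = 0.00347), and without knockout replicate 1 Col1a1 was not called (adjusted p = 0.0616). With 6 listed genes the list was too short for a rise to pass Fisher's exact test (adjusted p = 0.379). None of the 15 endothelial, 13 smooth muscle and pericyte, 12 seminal vesicle, 13 neuroendocrine or 9 red blood cell genes was among the 632, and these were not analysed here.

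Cell cycle genes rose from low levels. Of 37 on the list 6 were listed and all 6 rose, with a median of 3.11-fold, all 6 stayed higher on the scale centred on the listed genes, and adjusted over the list alone 6 passed. The proliferation marker Mki67 rose 3.42-fold from 0.260 ± 0.022 to 0.888 ± 0.247 FPKM, the mitotic genes Birc5 and Ccnb2 rose 3.28-fold and 3.11-fold, and the kinase gene Aurkb 3.10-fold from 0.536 ± 0.056 to 1.67 ± 0.75 FPKM. Birc5 was also the 1 listed gene of 17 YAP and TAZ targets, where adjusted over the list alone 1 passed. The cell cycle list was too short for a rise to pass Fisher's exact test (adjusted p = 0.379), and the rise of Aurkb did not pass without control replicate 2 or knockout replicate 1 (adjusted p = 0.0562 and 0.0521). Listed myeloid genes and listed B cell and plasma cell genes rose in the same libraries, and which cells carried the cell cycle genes was not tested.

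Among signalling lists the Wnt and beta-catenin list had 5 of 25 genes listed, of which 4 rose and Nkd1 was not called, and adjusted over the list alone 4 passed, while 2 of the 5 were lower on the scale centred on the listed genes. The members that rose were the secreted Wnt antagonist genes Sfrp4 (4.02-fold), Sfrp1 (2.32-fold) and Dkk3 (1.57-fold), and Cd44. The list was too short for a rise to pass Fisher's exact test (adjusted p = 1). Of 37 PI3K and growth factor genes 3 were listed, of which Igf1 (2.12-fold) and Igfbp4 (1.70-fold) rose and Egf fell from 110 ± 15.4 to 81.3 ± 9.79 FPKM, and adjusted over the list alone 2 rose and 1 fell. Igfbp4 was lower on the scale centred on the listed genes, and the fall of Egf did not pass without control replicate 1 or 2 or knockout replicate 2 or 3 (adjusted p = 0.0783 to 0.124). The rise of Dkk3 did not pass without control replicate 1 or 3 or knockout replicate 2 or 3 (0.0525 to 0.101) or on the midpoint scale (0.0626). Of 18 androgen-regulated genes 2 were listed, Steap4, which rose 2.27-fold, and Acsl3, at 33.3 ± 4.11 and 26.1 ± 2.39 FPKM and not called (called as fallen on the midpoint scale, adjusted p = 0.0225), and adjusted over the list alone 1 passed. Of 20 epithelial-mesenchymal transition genes 2 were listed, Cd44 and Mmp2, and both rose, while Mmp2 was lower on the scale centred on the listed genes and not called without knockout replicate 1 (adjusted p = 0.0553), and adjusted over the list alone 2 passed.

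Genes of dissociation stress and the immediate early response rose, with 4 of 24 listed, all 4 called and 4 passing adjusted over the list alone, while 1 of the 4, Ier3, was lower on the scale centred on the listed genes. Socs3, a feedback inhibitor of cytokine signalling, rose 3.88-fold, Egr1 3.67-fold from 2.73 ± 1.12 to 10.0 ± 1.05 FPKM, Fos 2.69-fold and Ier3 1.55-fold. On this list the knockout libraries were 1.08, 1.13 and 1.25 above the control mean on the log2(FPKM + 1) scale and control library 2 was 0.22 above it. These genes also mark stress of tissue digestion, an enzyme step that came before sorting here, and whether it differed between the groups is not given in the sources used here. Of 23 matrix protease and inhibitor genes 4 were listed and all 4 rose, namely Adam8 (3.25-fold), Plat (1.77-fold), Serpinb5 (1.76-fold) and Mmp2 (1.55-fold), with 4 passing adjusted over the list alone, while 3 of the 4 were lower on the scale centred on the listed genes. The rises of Mmp2 and Plat did not pass without knockout replicate 1 (adjusted p = 0.0553 and 0.0571), nor that of Plat without control replicate 1 (0.0531). Of 28 lipid and steroid genes 3 were listed, of which Apoe and the adipokine gene Adipoq rose and 1 was not called, and adjusted over the list alone 2 passed. Apoe was lower on the scale centred on the listed genes, and the rise of Adipoq, from 1.27 ± 0.38 to 3.70 ± 2.26 FPKM (1.89-fold without knockout replicate 1), did not pass without any 1 control replicate (adjusted p = 0.0638 to 0.101). Of 23 solute carrier and channel genes 3 were listed, of which Clca3a1 rose 3.18-fold and Atp12a and Slc26a4 were not called (Atp12a was called as fallen on the midpoint scale, adjusted p = 0.0255), and adjusted over the list alone 1 passed. Of 21 p53 and apoptosis genes 2 were listed, Pmaip1, which rose 3.53-fold, and Sesn2, not called, and adjusted over the list alone 1 passed. Without control replicate 1 Pmaip1 was not called (adjusted p = 0.0521), and without control replicate 2 Sesn2 was called as fallen (0.0463). Of 20 unfolded protein response genes 3 were listed, Asns, Chac1 and Trib3, with log2 ratios of -0.61, -0.61 and -0.63 and 0 called, adjusted over the list alone as well. On this list control library 1 was 0.81 above the control mean on the log2(FPKM + 1) scale, and without control replicate 2 limma called Chac1 as fallen. None of the 23 glycolysis and hypoxia genes was among the 632, and these were not analysed here.

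**Figure D3:**
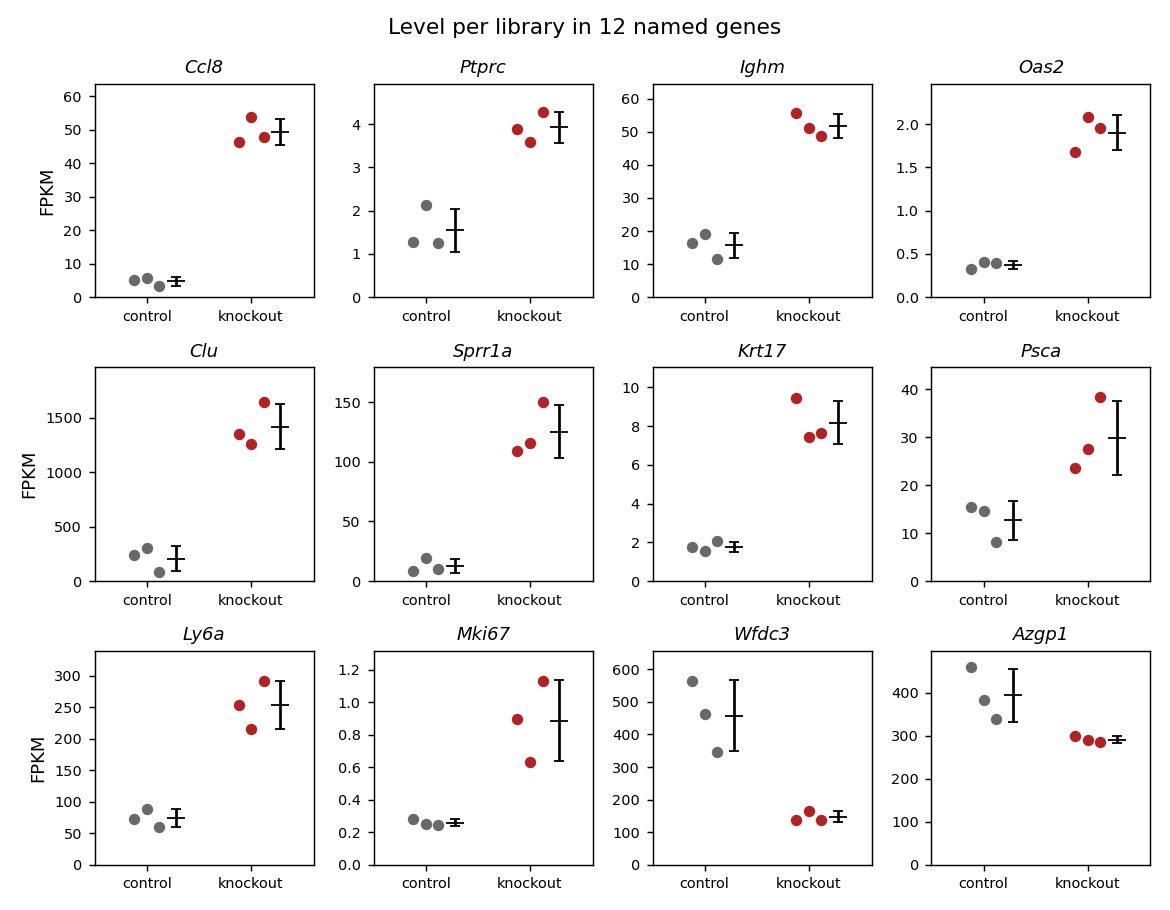
Points give the FPKM of each of the 3 control and 3 knockout libraries for 12 named genes, and the bars beside them the mean ± SD. The libraries of the 2 groups did not overlap for any of these genes, which were taken from called genes of a selected list, and Wfdc3 and Azgp1 are the 2 that were lower in knockout.

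Genes listed at 0 in a whole group were few. There were 9 genes at 0 in all control libraries, 8 of them immunoglobulin variable segments and the other the microRNA host gene Mir142hg, which had 8.44, 11.8 and 14.3 FPKM in the knockout libraries. The pseudogene Scgb2b4-ps was at 0 in all knockout libraries and at 5.90, 2.48 and 2.39 FPKM in the control libraries. These genes are named because there are few, and were chosen after their values were seen.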

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

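The adjustments over annotated genes, centring on the midpoint of the gap in log2 ratios, the form of centring used, unmoderated variances and the list tests without each library were chosen after the results had been seen. Rises outnumbered falls in each alternative except centring on the median ratio of the listed genes (a shift of 0.93). There 71 genes rose and 163 fell. About as many genes were lower (312) as higher (320), which centring on the list's own median fixes in advance. With the shift subtracted after the pseudocount, the form run first, 30 rose and 201 fell. In the form used, 14 of the 80 named genes reversed, with limma log2 differences of -0.053 (Apoe), -0.27 (Col1a2), -0.20 (Dkk3), -0.21 (Fbln1), -0.26 (Ier3), -0.15 (Igfbp4 and Krt14), -0.13 (Krt4), -0.0082 (Ly6e), -0.26 (Mmp2), -0.059 (Plat), -0.12 (S100a11), -0.078 (Serpinb5) and -0.32 (Thy1). In the first form 25 reversed, which adds Adam8, Aldh1a3, Aurkb, Ccnb2, Cd79b, Clca3a1, Col17a1, Cxcl2, Itgax, Mki67 and Mx2, so the choice of form lowered the number of reversals. Centring on the midpoint (a shift of 0.15) gave 390 rises and 119 falls (370 and 120 in the first form) and reversed 0 named genes. Adjustment over protein-coding genes left 23 rises and 1 fall, with 11 of the 80 named genes called, and over all annotated genes 1 and 0, because more genes count as tested. A threshold of 0.01 left 8 falls. At 5 FPKM or more 217 rose and 31 fell, of 245 higher and 161 lower, with fewer genes tested. No alternative kept only the most abundant genes, and at 100 FPKM and above 26 listed genes were higher and 48 lower. At a log2 ratio of at least 1, 267 rose and 12 fell, of 292 higher and 26 lower, and at least 2, 60 rose and 6 fell, of 71 and 13. Leaving out 1 library gave 365 to 410 rises and 20 to 79 falls, with 20 without control replicate 1 and 79 without control replicate 2, and 24, 25 and 22 without knockout replicates 1, 2 and 3. In all 6 of these fits 356 of the 459 calls were kept, 342 rises and 14 falls, with 67 of the 80 named genes. Fisher's exact test passed 2 lists, 0 at a log2 ratio of at least 1 and 0 among genes at a limma adjusted p of 0.01, where too few falls remain for a rise to pass, and 0 (without control replicate 1) to 3 (without knockout replicate 1) with 1 library left out. Camera over the listed genes passed 2 lists with its preset correlation, chosen after the results had been seen, and 0 with an estimated correlation. The estimates ranged from 0.0286 (Wnt and beta-catenin list) to 0.697 (stem and progenitor list). Without control replicate 1 all 15 myeloid and 16 interferon genes stayed higher, while the other listed genes that were lower went from 182 to 170. The adjusted p of these 2 lists thus moved through the other listed genes and the adjustment over lists, not through their members. The cause of the other shifts between libraries was not tested. Below 0.1 FPKM were 15 genes in control and 3 in knockout, against 9 and 1 at 0. The larger size of rises held with pseudocounts of 1 and 0.1, at 1 FPKM or more and on the midpoint scale (difference in median absolute log2 ratio 0.40 to 0.72). Count models and the Cdh1 alternatives were not run, as they need counts or Cdh1. Depth is unknown, so its limit on low genes could not be set.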

Other observations

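All tests in this part except that of genes near Cdh1 were chosen after the results had been seen, and the 4 gene lists first used here were written then. Genes of squamous and cornified epithelium were mostly higher in knockout libraries. Of 17 on that list 10 were listed and 8 rose, 8 also adjusted over the list alone, while 3 of the 10 were lower on the scale centred on the listed genes. Besides Sprr1a and Krt17, Prr9 rose 5.47-fold from 5.39 ± 1.56 to 29.5 ± 6.90 FPKM (n = 3 per group, limma adjusted p = 0.0016), Ly6d 4.39-fold and the galectin gene Lgals7 2.49-fold. Without knockout replicate 3 Spink5 was called as well (adjusted p = 0.0258). Csta1 was at 3.32 ± 1.32 and 1.55 ± 1.01 FPKM and not called. Of 16 complement genes 13 were listed and 11 rose, 11 also adjusted over the list alone, while 2 of the 13 were lower on the scale centred on the listed genes. Complement factor B (Cfb) rose 3.99-fold, C4b 3.21-fold and C3 2.63-fold from 13.8 ± 2.52 to 36.2 ± 5.61 FPKM. C3 is also on the acute phase list, and some other members are on the myeloid or adipocyte list, so these counts overlap. Of 8 adipocyte genes 4 were listed, all higher and 1 called, Adipoq, and 0 passed adjusted over the list alone. The number called was 0 without control replicate 2 or 3 and 3 without knockout replicate 3, and without control replicate 1 it was 1, Thrsp and not Adipoq. On this list knockout library 1 was the highest. Knockout libraries 2 and 3 were 0.71 and 0.36 above the control mean on the log2(FPKM + 1) scale, and control library 1 was 0.36 above it.

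Of the immunoglobulin genes 29 were listed, all higher on each scale tried, and 20 were called by limma as risen. Among genes with names of interferon-induced families, 34 were listed and 33 rose, with a median of 2.21-fold, while 8 of the 34 were lower on the scale centred on the listed genes. All 8 listed genes of the class II histocompatibility pathway rose, with 1 lower on that scale. All 6 listed secretoglobins were lower on each scale tried and 5 fell by limma. The 4 listed annexins rose, with 3 lower on the scale centred on the listed genes. Families were grouped by gene name after the values were seen, on a list selected for differences. Serpina3n, a serine protease inhibitor gene, rose 9.49-fold and the protease gene Ctse 9.69-fold.

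Of the 10 splits of the 6 libraries into groups of 3, 1, the real one, gave as many calls as the 459 of limma, and the highest other gave 0. With 10 splits no share under 0.1 can be reached, and the genes had been selected on the real split.

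Leukocyte and fibroblast markers were both higher in knockout libraries, although the cells had been sorted as epithelium. A lower epithelial share that raises every other cell type alike is argued against for the listed genes. Per library, their mean log2 level, myeloid minus fibroblast, was 0.36 to 0.45 above the control mean in the knockout libraries. In the control libraries it was between -0.01 and 0.01. The median log2 ratio of listed myeloid genes exceeded that of listed fibroblast genes by 0.474 (two-sided exact permutation test over 15 and 6 genes, p = 0.00066). That test takes genes as independent, while the correlation estimated between members was 0.642 for the myeloid and 0.421 for the fibroblast list. Both sets are limited to selected genes. More leukocytes among the sorted cells of the knockout libraries may account for the myeloid genes and remains open, as 0 of the 15 listed myeloid genes were lower, with Cd74 at 140 ± 30.5 and 300 ± 8.08 FPKM and Lyz2 at 59.5 ± 2.51 and 113 ± 6.23. Expression in the epithelial cells themselves was not tested and also remains open for genes such as Cd74. A processing batch marked by L2 and L7 cannot be told apart from genotype, as 0 groups hold both marks.

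Genes of the ATF4-linked amino acid response were lower in the knockout libraries, with 16 of 23 listed, all 16 lower, a median log2 ratio of -0.61 and 1 called, Gdf15, which fell from 25.6 ± 5.04 to 15.4 ± 0.83 FPKM, and 0 called when adjusted over the list alone. Without control replicate 2, the lowest control for the list, 5 were called, with Chac1, Eif4ebp1, Nupr1 and Sesn2 added, and on the midpoint scale 2, with Eif4ebp1 added. Gdf15 was highest in control library 3 and kept a log2 ratio of -0.57 without it. Asns, Chac1 and Trib3, the listed unfolded protein response genes, and Sesn2 of the p53 list are among the 16, so these lists overlap. For the list as a whole, a loss against each control library is argued against, since the lowest median log2 ratio of a control library over the knockout mean was -0.077, for control library 2 (0.07 on the midpoint scale). A high level in control library 1 may account for most of the median, which was -0.04 without it, a share of 0.0664 of its size, and this library was the highest of the 6 for 15 of the 16 genes. That it acts alone remains open, as control library 3 also lay above the knockout mean by a median log2 ratio of 0.28 (0.43 on the midpoint scale).

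Log2 ratios left a gap that is centred above 0, with 3 of the 632 genes between -0.25 and 0.5. Lower power at low levels would not by itself make rises start higher than falls at high levels, as they did here. At 100 FPKM and above, the 10% quantile of absolute log2 ratios was 0.407 higher for 26 rises than for 48 falls (95% bootstrap interval over genes 0.313 to 0.613), against 0.359 at 1 to 10 FPKM (0.260 to 0.435). The difference at 100 FPKM and above was 0.399 at the 5% and 0.566 at the 25% quantile. A count of genes inside the gap, the test run first, was replaced because the gap was defined on the same genes. The quantiles share this limit for the rises, since the gap holds only 3 genes and few rises at any level could start inside it. They describe the gap at high levels and are not an independent test of its cause. A selection made on another scaling than the deposited values may explain it, since the midpoint was 0.134 at 1 to 10 FPKM, the lowest of 3 levels, and 0.141 and 0.152 above. These midpoints leave out the 3 genes inside the gap. With them, 0 of 96 falls at 10 to 100 FPKM were smaller than the smallest rise, so the midpoint at that level depends on leaving them out. Unequal limits for rises and falls in the selection would give the same gap, so this remains open. No biological explanation was tested.

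A segment around Cdh1 carried along with the conditional allele would place an excess of listed genes near it. Within 10 Mb of Cdh1 lay 1 of 573 listed protein-coding genes, Hp, 0.175%, against 172 of 21377 unlisted ones, 0.805% (two-sided Fisher's exact test, p = 0.142), so no excess was seen and the number of genes is too small to exclude one.

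Some listed falls rest on 1 control library. Of 181 falls with a finite ratio, 19 turned to rises without their highest control library, which was control library 1 for 13 of them. They include amino acid response genes described above, such as Trib3. Leaving out the highest control makes any fall smaller, so small falls can turn through ordinary scatter, and no matching count is given for rises. In 10 of the 181 falls the highest control was over 5 times the second. Arhgap27 was at 733, 5.79 and 5.72 FPKM in the control libraries and at 8.43 ± 0.86 in knockout, and Cisd3 at 680, 30.4 and 31.3 against 33.0 ± 0.53, and limma called neither.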
